A study of Arabidopsis thaliana with 8 samples.

How the data were processed

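RNA of wild-type Arabidopsis thaliana (WT, ecotype Columbia 0) and of the tic40 mutant in the same ecotype was measured on 1-colour expression arrays, 4 samples per genotype, numbered 1 to 4 in the labels. TIC40 is a component of the protein import machinery of the inner chloroplast envelope. The labels do not give the tissue, the age or the growth conditions, and they do not say whether the samples came from separate plants. The p-values therefore measure only the spread between these samples, which may be technical.

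The deposited table holds 1 value per probe and array for 3439 probes. From the values, the deposited numbers are intensities on a linear scale, never negative, with means per array of 1.03 to 1.12, which is a relative scale. The scanner, the background correction and the scaling behind these intensities are not given in the sources used here. Between 174 and 277 probes per array are listed at exactly 0. On WT samples 1 and 2, 2 probes stand at 99.999999999. This may be the highest value the field can hold, in which case their levels there are lower bounds, but the sources used here do not say so. Arrays have no sequencing depth, and the number of arrays limits the precision.

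The test, the samples, the gene lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. The rule for scaling was to keep the table as deposited if the 8 column medians lay within 0.1 on the log2 scale, and to apply quantile normalization between arrays otherwise. The log2 medians, taken over the values above 0 of each array, spanned 0.72, so quantile normalization was used. Quantile normalization whatever the medians, listed beforehand as another setting, is thus the setting reported. Exact zeros were set after scaling to a floor, percentile 1 of the positive values of that array, which lay between 0.0147 and 0.0665. WT samples 1 and 2 had the highest floors, so a difference between dim signals depends on it. The 121 probes at 0 on all 8 arrays were left out and 3318 were tested, of which 3083 lay above 0 on every array. Levels are given below as normalised intensities, mean ± SD over the 4 samples of a genotype. A fold is 2 to the power of the fitted log2 difference, tic40 minus WT, so it can differ from the ratio of the means.

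Differences were fitted per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the genotype as the only term. The test was two-sided, with Benjamini-Hochberg adjustment over all probes tested and a call at an adjusted p under 0.05. On simulated data with 200 of 3318 probes changed and independent samples, the procedure recovered 53.5% of 2-fold changes with 4.46% false calls, and 88% of 4-fold changes with 5.88% false calls.

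The same sample numbers occur in both genotypes, and the labels do not say that they mark a shared batch or day. As a check, the deviations of each sample from its genotype's mean were correlated across probes. Same-numbered WT and tic40 samples correlated at 0.306, 0.310, 0.261 and 0.254 for numbers 1 to 4, while the highest correlation of each WT sample with a tic40 sample of another number was 0.0497, 0.0295, 0.120 and 0.0990. Every pair lay above 0.1, so the numbers were taken to pair the samples. The fit with the number as a replicate block is given in the paragraph of each result whose call it changes.

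Gene names came from the platform annotation. A single gene was named for 692 probes, several genes for 870, and none for 1877. Of the 692 single names, 690 were found in the TAIR10.1 gene table, which was used for names only. No coordinates are printed because the build behind the probes is not given. Among tested probes, 663 had a single gene name. No gene is named from a probe with several genes. The rule named the 10 largest rises and the 10 largest falls among called single-gene probes whose 4 tic40 values all lay on one side of all 4 WT values after zeros had been set to the floor, and in each gene list the 4 members with the lowest p.

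Of 20 gene lists with 372 members fixed beforehand, single-gene probes measured 16 members, and only the plastid ribosomal proteins reached the minimum of 4 for a list test. A check of the list members against the reference names dropped 11 of them, none of which a probe measured. After the probes' gene names had been seen, and before any test, 4 further lists were pooled from those names, covering photosynthesis, plastid biosynthesis and redox enzymes, organelle RNA processing and translation factors, and developmental regulators. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, and adjusted within the fixed and within the added lists. No probe of the annotation names TIC40, so the test of its level fixed beforehand was not made and its expression is not analysed here.

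The alternative settings fixed beforehand were the replicate block, the table as deposited, centring each array on its median, leaving out the 830 probes in the dimmest 25%, an offset of 0.145 before log2, the trend and robust options of eBayes, array quality weights, an ordinary 2-sample test with equal variances, and leaving out each sample in turn. Alternatives added after the arrays had been seen were other treatments of the floor and of zeros, fits without WT samples 1 and 2 or 3 and 4, fits of samples 1 and 2 or of samples 3 and 4 alone, and fits that treat samples 1 and 2, and samples 3 and 4, of a genotype as repeats (averaged, as random blocks, or as a fixed block shared by both genotypes).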

Results

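The comparison asks which transcripts differ between tic40 plants, which are impaired in protein import across the inner chloroplast envelope, and WT plants. Each genotype was measured on 4 arrays. The median deposited intensity per array was 0.361, 0.354, 0.559 and 0.564 for WT samples 1 to 4, and 0.602, 0.604, 0.568 and 0.575 for tic40 samples 1 to 4. After quantile normalization the WT arrays fell into 2 pairs. WT samples 1 and 2 correlated with each other across probes at 0.947 and WT samples 3 and 4 at 0.946, while the correlations between these pairs were 0.707 to 0.722. The 4 tic40 arrays correlated at 0.934 or above. WT samples 1 and 2 correlated with the tic40 arrays at 0.874 to 0.907, which is higher than with the other WT arrays, and WT samples 3 and 4 correlated with tic40 at 0.739 to 0.800.

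**Figure D1:**
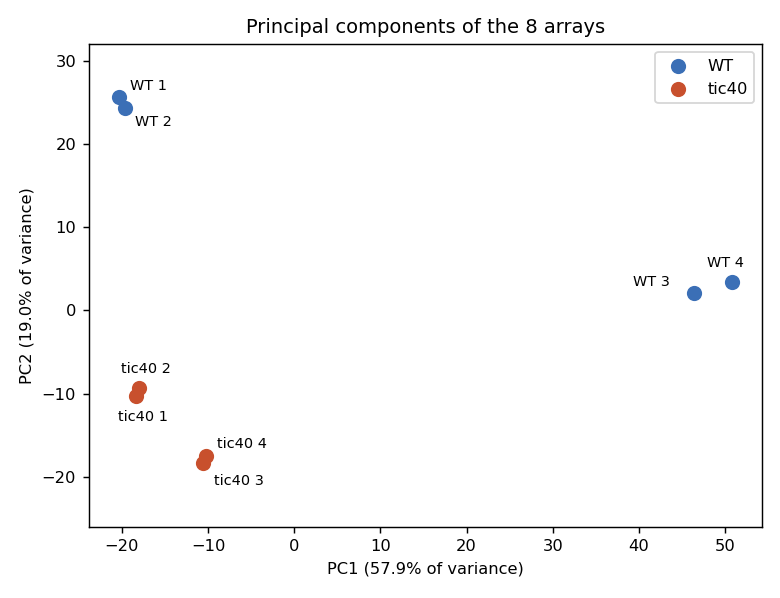
Principal components of the normalised log2 intensities of the 8 arrays, 1 point per array, with WT in blue and tic40 in red. PC1 (57.9% of the variance) sets WT samples 3 and 4 apart from the other 6 arrays, and PC2 (19.0%) sets WT samples 1 and 2 apart from tic40.

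Of the 20 ranked genes, those with the largest rises in tic40 were AT5G06930 and AT3G56810. AT5G06930 went from 0.204 ± 0.163 in WT to 1.16 ± 0.0745 in tic40 (SD, n = 4 each; log2 difference 2.99 with SE 0.63, limma adjusted p = 0.0298), but its values in WT samples 1 and 2 were listed at 0, so that difference depends on the floor. AT3G56810 went from 0.288 ± 0.194 to 0.982 ± 0.168 (log2 difference 2.04, adjusted p = 0.0452). AT3G17950 (1.17, adjusted p = 0.0247) and AT3G44610, which encodes a protein kinase (1.06, adjusted p = 0.0124), rose by over 2-fold. The 6 smaller rises had log2 differences of 0.94 for AT2G47680, 0.93 for AT4G33540, 0.74 for AT5G03900, 0.69 for AT4G27250, 0.68 for AT3G21810 and 0.54 for AT1G61990, a member of the mTERF family of organelle nucleic acid binding proteins. Their adjusted p-values lay between 0.0224 and 0.0446. With the replicate block none of the 10 rises passed (adjusted p of 0.0609 to 0.0915), and AT3G17950, AT3G44610, AT2G47680, AT5G03900 and AT3G21810 were those that passed under both other scalings. Of these, AT2G47680 (limma adjusted p = 0.0983) and AT3G21810 (adjusted p = 0.0612) did not pass in samples 1 and 2 alone. The log2 differences of AT5G06930 were larger as deposited and with median centring, 4.05 (adjusted p = 0.0587) and 3.70 (adjusted p = 0.0657), and those of AT3G56810 were 2.48 (adjusted p = 0.0150) and 2.13 (adjusted p = 0.0516). AT4G33540 had 1.12 (adjusted p = 0.00897) and 0.77 (adjusted p = 0.0596), AT4G27250 0.75 (adjusted p = 0.0651) and 0.40 (adjusted p = 0.0936), and AT1G61990 0.82 (adjusted p = 0.0632) and 0.47 (adjusted p = 0.0859).

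Among the falls, AT1G09200, a gene for histone H3.1, went from 0.317 ± 0.0436 to 0.116 ± 0.0203 (log2 difference -1.45 with SE 0.18, adjusted p = 0.00832). Its probe can also bind transcripts of the near-identical H3.1 genes. AT4G05030 fell with the same adjusted p, from 0.237 ± 0.0394 to 0.0836 ± 0.0139, as did AT1G49870 (-1.41), AT5G59060 (-1.36) and AT4G30740 (-1.29). AT2G45990 fell by 1.26 on the log2 scale (adjusted p = 0.0124). AT5G06410, which encodes the HscB co-chaperone of iron-sulfur cluster assembly, fell by 1.33 on the log2 scale (adjusted p = 0.0300), and GH9B8, a glycosyl hydrolase of family 9, by 1.31 (adjusted p = 0.0298). AT1G76450, which encodes a PsbP-domain protein, was listed at 0 on all 4 tic40 arrays and on 2 WT arrays, so no fold is given. AT3G45770, an enoyl-acyl carrier protein reductase gene of mitochondria, lay near the floor in both genotypes (0.0620 ± 0.00637 in WT and 0.0187 ± 0.0108 in tic40, adjusted p = 0.0409), and its difference was 0.00 with 1 common floor for all arrays. With the replicate block none of the 10 falls passed (adjusted p of 0.0527 to 0.0799). Only AT4G05030, AT5G59060 and AT4G30740 passed under both other scalings. As deposited, AT1G09200 had a log2 difference of -0.80 (adjusted p = 0.103), AT1G49870 -0.57 (adjusted p = 0.200), AT2G45990 -0.57 (adjusted p = 0.158), GH9B8 -0.53 (adjusted p = 0.192) and AT5G06410 -0.76 (adjusted p = 0.110). Median centring kept the calls of AT1G09200 (-1.15, adjusted p = 0.0134), AT1G49870 (-0.92, adjusted p = 0.0353) and AT2G45990 (-0.92, adjusted p = 0.0301). It did not keep those of GH9B8 (-0.88, adjusted p = 0.0569) and AT5G06410 (-1.11, adjusted p = 0.0540). AT1G76450 and AT3G45770 passed under neither.

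**Figure D2:**
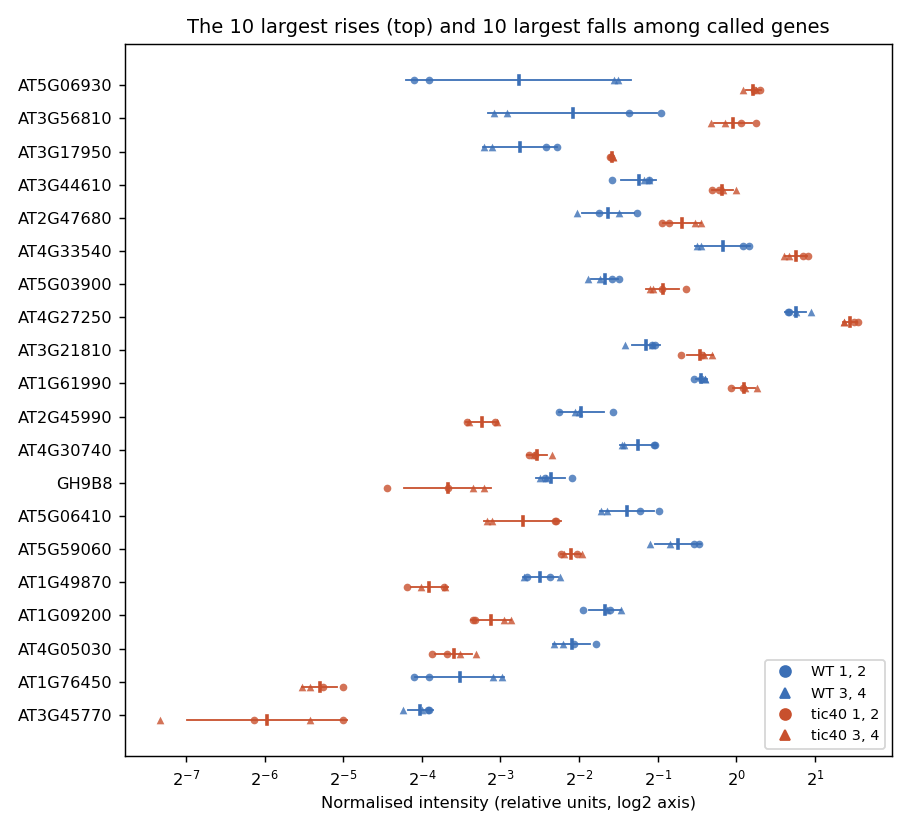
Normalised intensity of the 10 largest rises and the 10 largest falls on a log2 axis, with 1 point per array (circles for samples 1 and 2, triangles for samples 3 and 4), the mean of the log2 values as a vertical tick and 1 SD as a horizontal line. All 4 tic40 values (red) lie on one side of all 4 WT values (blue) as plotted, but points of arrays listed at 0 are only their floors. These are all tic40 arrays and WT samples 1 and 2 for AT1G76450, WT samples 1 and 2 for AT5G06930, and WT sample 2 and tic40 samples 2 and 4 for AT3G45770. AT5G06930 (WT 0.204 ± 0.163) shows the widest WT spread among the rises on this axis, which includes its floors.

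Smaller falls that passed the test were chosen here after their values had been seen, for genes with well-known products. CCS, the copper chaperone for superoxide dismutase, went from 0.209 ± 0.0151 to 0.138 ± 0.00797 (log2 difference -0.59, adjusted p = 0.0298). LpxA, an acyltransferase of lipid A-type synthesis, went from 1.57 ± 0.303 to 0.730 ± 0.110 (-1.10, adjusted p = 0.0204). AT1G68660, which encodes the ClpS1 adaptor of the plastid Clp protease, went from 0.865 ± 0.0480 to 0.543 ± 0.0148 (-0.67, adjusted p = 0.0208). With the replicate block none of these 3 passed (adjusted p of 0.0758 for CCS, 0.0728 for LpxA and 0.0673 for AT1G68660). Falls depended on the scaling, with 178 probes called lower after quantile normalization and 46 as deposited, and the values of these 3 genes under other scalings are not given here.

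In all, limma called 255 of 3318 probes, 77 higher and 178 lower in tic40, and 803 had an unadjusted p under 0.05. The count was 43, 45, 54 and 44 without tic40 samples 1 to 4 in turn, 127 without WT sample 3 and 122 without WT sample 4. Of the 41 called probes with a single gene name, 11 were higher and 30 lower, and 14 were also called both as deposited and with median centring. Zeros on some arrays make the folds of 4 of them depend on the floor, and the other 37 had folds of 1.41 to 4.11 for the 10 rises and up to 2.83 for the 27 falls. With the sample number as a replicate block 5 probes were called, 4 higher and 1 lower, 4 of them among the 255, and none of the 41 single-gene probes passed, although 884 probes had an unadjusted p under 0.05. With samples 1 and 2, and samples 3 and 4, averaged within each genotype, limma called 0 probes and 184 had an unadjusted p under 0.05. The split by direction depended on the scaling: without quantile normalization 357 probes were called, 311 higher and 46 lower, with the median log2 difference of all probes at 0.32, and 81 of the 255 probes (42 higher, 39 lower) were called under all 3 scalings.

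The 5 probes called with the replicate block, which are named because they are few and after their values had been seen, carry no single gene name. Probe 1142 went from 1.32 ± 0.175 to 6.26 ± 0.454 (log2 difference 2.25, adjusted p = 0.000646, and 0.0389 with the block). Probe 1259 went from 0.965 ± 0.167 to 4.09 ± 0.266, probe 2674 from 0.649 ± 0.0864 to 2.22 ± 0.0692, and probe 1733, annotated with 2 genes, from 1.03 ± 0.0569 to 3.53 ± 0.166. Probe 3698 had a log2 difference of -1.56 (SE 0.42) and passed only with the block (adjusted p = 0.0604, and 0.0443 with the block). In simulated draws where samples 1 and 2, and samples 3 and 4, of a genotype shared their deviations, with no genotype effect, the block gave 19 to 115 calls, more than these 5. Those draws understated the shared deviation, gave both genotypes the same spread and left out the correlation of same-numbered samples, so the comparison is only rough. Among unnamed probes ranked by size, probe 3280 had the largest rise (2.28, adjusted p = 0.0223), and probes 3102 and 2007 the largest falls, near the floor, with calls that were lost with 1 common floor. With the replicate block these 3 did not pass (adjusted p = 0.0642, 0.0654 and 0.115 for probes 3280, 3102 and 2007).

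Of 12 photosynthesis genes with a single-gene probe 1 rose, 0 fell and 11 did not pass, and adjusted over the list alone 1 rose and 1 fell. CCB3 was listed at 0 on all 4 WT and on 3 tic40 arrays, and PIFI on 1 WT array. Their differences depend on the floor, and both entered the list median and the list tests. The gene that rose was PSBW, the W subunit of photosystem II, from 17.0 ± 0.953 to 24.0 ± 1.42 (log2 difference 0.50 with SE 0.12, adjusted p = 0.0479). Its rise rested on the scaling, since the log2 difference was 0.04 (adjusted p = 0.960) with median centring and 0.39 (adjusted p = 0.355) as deposited, and its adjusted p was 0.0923 with the replicate block. LHB1B2, a light-harvesting antenna protein of photosystem II, was at 7.40 ± 3.71 in WT and 2.65 ± 0.190 in tic40 (adjusted p = 0.0614), with WT means of 10.6 in samples 1 and 2 and 4.21 in samples 3 and 4. Tested within samples 1 and 2 its log2 difference was -2.06 (adjusted p = 0.0103), and within samples 3 and 4 it was -0.61 (adjusted p = 0.0310). These fits of 2 against 2 arrays measure only the spread within such pairs, and they called 1012 and 2000 of 3318 probes. With the replicate block the limma adjusted p of LHB1B2 was 0.103. The log2 differences of PSBY (-0.40, adjusted p = 0.120), PSB27 (-0.42, adjusted p = 0.522) and PSAN (-0.26, adjusted p = 0.479) and of the Calvin cycle enzymes PRK (-0.90, adjusted p = 0.137) and SBPASE (0.21, adjusted p = 0.360) did not pass. The median log2 difference of the 12 genes was -0.16 (camera adjusted p = 0.741, and 0.739 with an estimated correlation). Without comparing the list with other genes, fry gave an adjusted p = 0.185 for a shift one way on balance and an adjusted p = 0.000615 for change in either direction.

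Plastid ribosomal proteins were the only group fixed beforehand with enough measured members, 5 of 39. AT1G64510, the gene for plastid ribosomal protein S6, fell from 0.183 ± 0.0233 to 0.0929 ± 0.0151 (log2 difference -0.98, adjusted p = 0.0209, and 0.0655 with the replicate block), both over all probes and adjusted over the list alone. Its values under other scalings are not given here. The other 4 did not pass: AT3G13120 (S10) -0.54, AT1G29070 (L34) -0.52, AT3G54210 (L17) -0.14 and AT4G01310 (L5) 0.08. AT1G29070 was listed at 0 on 1 WT and 1 tic40 array, so its difference (SE 0.60) depends on the floor. Its sign was opposite in the pairs of samples fitted alone, without passing in either. Its value is also the list median, and it entered the list tests. The median of the 5 was -0.52 (camera p = 0.119, and p = 0.163 with an estimated correlation), while fry, which asks only whether the genes moved one way on balance, gave p = 0.000547 (adjusted p = 0.00587 for change in either direction).

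None of the 7 organelle RNA processing and translation factors passed, with a median of 0.27 (camera p = 0.0819, adjusted p = 0.328, adjusted p = 0.494 with an estimated correlation, fry adjusted p = 0.0506 one way and adjusted p = 0.234 in either direction, the latter 0.0394 with the replicate block). Their values included 0.35 for OSB1, an organellar single-stranded DNA binding protein (adjusted p = 0.132), 0.88 for AT5G55580 (mTERF9), 0.41 for CRR21 and 0.20 for OTP85. None of the 13 plastid biosynthesis and redox genes passed (median -0.06, camera adjusted p = 0.741, fry adjusted p = 0.206 one way and adjusted p = 0.234 in either direction). SIRB, a ferrochelatase of sirohaem synthesis, came closest at -0.69 (adjusted p = 0.0533), followed by AT5G58330, the NADP-dependent malate dehydrogenase of plastids, at -0.50 (adjusted p = 0.128). AT3G52960, a type II peroxiredoxin, had a difference of 1.08 (adjusted p = 0.304), CHLM, a methyltransferase of chlorophyll synthesis, 0.10 (adjusted p = 0.802), AT-HF, an enzyme of histidine synthesis, -0.40 (adjusted p = 0.464) and AT1G74470, the geranylgeranyl reductase, 0.01 (adjusted p = 0.979). Cpn60beta3, a plastid chaperonin subunit, stood at 0.79 (adjusted p = 0.111). None of the 8 developmental regulators passed (median 0.10, camera adjusted p = 0.741, fry adjusted p = 0.959 one way and adjusted p = 0.193 in either direction, the latter 0.0103 with the replicate block), with AGL54 at -0.48, LAS at -0.59, DME at 0.61 and SPL at 0.75. Of the 24 listed plastid protein import genes, 0 were measured by a single-gene probe.

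Tested in samples 1 and 2 alone, limma called 1012 probes, 448 higher and 564 lower in tic40, and in samples 3 and 4 alone 2000, 841 higher and 1159 lower. Of the 37 called single-gene probes with no zero, 34 passed in both, 8 higher and 26 lower, which their choice from the calls over all 8 arrays favours. AT3G56810 rose by 1.32 in samples 1 and 2 and 2.76 in samples 3 and 4, and AT3G17950 by 0.75 and 1.59 on the log2 scale. AT5G06930 rose by 1.70 in samples 3 and 4, and no size is given for samples 1 and 2, where both WT values were listed at 0. Over all tested probes the fold changes of these pairs correlated at r = 0.131 (Spearman's rho 0.0977, across probes, which are not independent replicates), and 52.7% had the same sign. Both calls went the same way at 343 probes and opposite ways at 245. Called higher in both were 135, against 114 for independent lists (95% range 97 to 130), and called lower in both 208, against 197 (177 to 217). Opposite calls were fewer than in independent lists, with 135 higher in samples 1 and 2 and lower in samples 3 and 4 against 156 (138 to 175), and 110 the other way against 143 (125 to 162). Among the 3083 probes above 0 on all arrays the overlap was 130 against 108 (92 to 124) for rises and 191 against 170 (151 to 189) for falls. The overlap thus lay above the range for rises in both sets, and for falls only without the probes listed at 0 on some array. These ranges treat probes as independent.

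**Figure D3:**
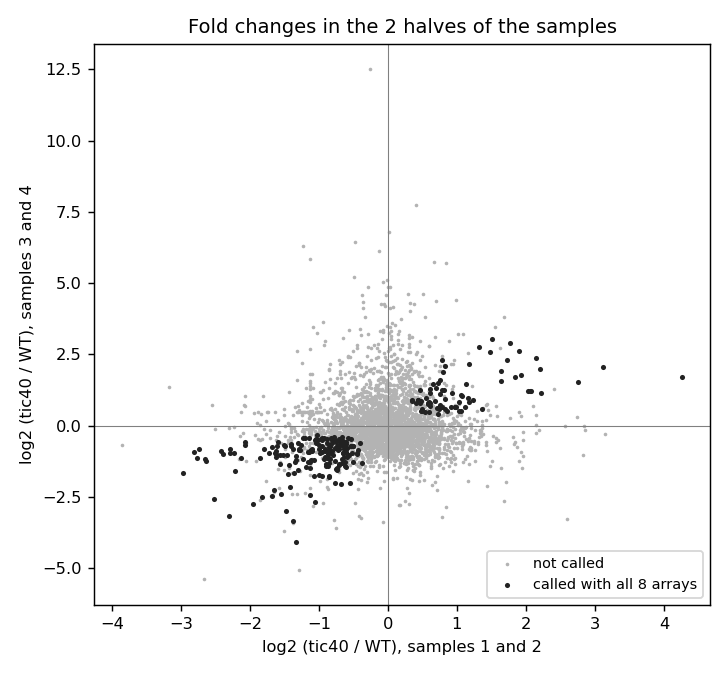
Log2 fold change (tic40 over WT) of each tested probe in samples 1 and 2 (horizontal) and in samples 3 and 4 (vertical), with the 255 probes called from all 8 arrays in black and the others in grey. Over all probes the correlation is 0.131; the black points lie where the signs are equal because their genotypes do not overlap, which the plot therefore does not test.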

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

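Tests of rank correlation, of a label swap, of the overlap of calls and of a shared deviation were chosen only after the results had been seen, and the tests of other splits, of a shared batch and of dim probes before.

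WT samples 3 and 4 stood apart from WT samples 1 and 2, with 1816 probes called between these pairs and an SD of the differences of 1.25, against 602 probes and 0.537 between the matching tic40 pairs. A batch shared by samples 3 and 4 of both genotypes would carry over to tic40, but the tic40 difference had a slope of only 0.108 on the WT difference (0.136 at most over array pairings). Rank correlations, which no monotone scaling changes, reached 0.719 between the WT pairs against at least 0.874 between WT samples 1 and 2 and tic40, and among the brightest 25% of probes the values were 0.651 and 0.839, so neither scaling nor dim signals explain it alone. A swap with tic40 would need a tic40 array closer to WT samples 3 and 4, and the highest such correlation was 0.800 against at least 0.934 among tic40 arrays. A WT-only difference in growth, RNA or hybridisation, or a wrong label involving a sample outside the series, may be the source and was not tested, and the design names no biological difference between the WT pairs.

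The 255 calls exceeded those of every other split of the samples, with 1 of the 35 splits into 4 and 4 giving as many and 31 in the highest other, which grouped samples 1 and 2 of both genotypes against the rest. This would exclude chance only for 8 independent samples. Samples 1 and 2, and samples 3 and 4, of a genotype correlated closely, so splits that part them place near-copies on both sides. Such splits were likely to call few or no probes whatever the genotype did. The splits that keep these samples together called 255, 31 and 0, and are too few for a share under 0.05. Of the 8 splits that part all 4 number pairs, as the real one does, the others called 0, but 8 splits are too few for a share under 0.05. Samples 1 and 2, and samples 3 and 4, of a genotype may however be repeats of 1 source, and simulated draws with such shared deviations and no genotype effect called 100 to 188 probes against 255 in the real samples, and 19 to 115 with the replicate block against 5. The draws understated the shared deviation and gave both genotypes the same spread, while the SD between the pairs was 1.25 in WT and 0.537 in tic40. They also left out the correlation of same-numbered samples across genotypes. Their counts therefore do not decide between repeats of this kind and a genotype effect, which cannot be told apart for single probes.

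Calls made in both samples 1 and 2 and samples 3 and 4 exceeded independent lists for rises, 135 against 114, also among probes above 0 on all arrays (130 against 108). For falls, 208 against 197 lay within the range of independent lists and 191 against 170 among probes above 0 on all arrays just above it, while 110 probes called lower in samples 1 and 2 and higher in samples 3 and 4, against 143, lay below. The counts go against independent calls for rises. For falls the shared calls over all tested probes do not. The low count of 110 opposite calls goes against independence by the rule chosen after the results had been seen, but it concerns rises in samples 3 and 4 as much as falls in samples 1 and 2. The arrays were quantile normalized together and probes are not independent, so the excess is not a measure of an effect of the mutation.

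Single arrays that stood away from the other 3 of their genotype, by the gap to the nearest value over the whole range, were found in 7 of 106 tests, and chance gives about 1 in 20. AT3G44610 was low in WT sample 1 (0.335 against a mean of 0.457, gap 0.872 of the range), AT3G21810 low in WT sample 3 (0.375 against 0.480, gap 0.890) and PSAN low in WT sample 3 (1.24 against 1.76, gap 0.860). AT3G13120 was low in WT sample 2 (0.130 against 0.262, gap 0.911). In tic40, LHB1B2 was high in sample 4 (2.93 against 2.56, gap 0.833) and SBPASE high in sample 1 (0.863, gap 0.843). Probe 2007 was flagged in tic40 sample 3 (0.00445 against 0.0269, gap 0.852), but the other 3 values are floors of arrays listed at 0. Sample 3 was its only tic40 array above 0, so this flag comes from the floor.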

How the results depend on the processing

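Alternatives that regroup or leave out pairs of samples, and those on zeros and the floor, were chosen after seeing the data. The count of 255 (77 higher, 178 lower) stayed within 1.5 times under median centring (237), without the dimmest 25% (208), with an offset (252), with trend and robust (237), with the ordinary test (251), with every value under the floor set to it (273), with 1 common floor (299) and with only probes above 0 throughout (257). It became 5 (4 higher, 1 lower) with the replicate block, 643 (349, 294) with array weights, whose estimation stopped before converging, 571 (212, 359) with samples 1 and 2 against 3 and 4 as a fixed block, 985 (470, 515) without WT samples 3 and 4, 1833 (814, 1019) without WT samples 1 and 2, 1012 (448, 564) in samples 1 and 2 alone, 2000 (841, 1159) in samples 3 and 4 alone, and 0 (0, 0) in limma with repeats averaged (184 at an unadjusted p under 0.05) or as random blocks (248). As deposited it was 357 with 311 higher and 46 lower, 87.1% higher against 30.2%. Leaving out 1 sample gave 43 to 240 (10 to 75 higher, 33 to 165 lower): 127 without WT sample 3, 122 without WT sample 4, and 43, 45, 54 and 44 without tic40 samples 1 to 4. Fewer samples lower the power of these fits; otherwise the cause was not tested. No list changed its side of the threshold in camera under any alternative run, the replicate block included. Of the genes named by the rule fixed beforehand, together with the unnamed probes ranked by size, 26 were called. Of these 25 lost the call with the replicate block, 13 with median centring and 14 as deposited. The call was lost by 20, 17, 18 and 19 without tic40 samples 1 to 4 in turn and by 8, 9, 14 and 14 without WT samples 1 to 4. All 26 lost it with repeats averaged or as random blocks. AT1G74470 passed without WT samples 3 and 4, at -0.48 (limma adjusted p = 0.0307), against 0.01 (adjusted p = 0.979) with all samples. Its WT mean was 1.84 in samples 1 and 2 and 0.927 in samples 3 and 4, on either side of 1.28 and 1.35 in tic40. The change thus follows the difference between the WT pairs, whose source was not tested. The deposited intensities carry no background signal, so a limit of detection other than the listed zeros is unknown.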

Other observations

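Samples 3 and 4 alone gave 2000 calls among 3318 probes, and samples 1 and 2 alone 1012. Of the 7 organelle RNA processing and translation factors, 5 rose in samples 3 and 4 and 0 fell, among them AT5G55580 (mTERF9, log2 difference 2.19), ATAB2 (1.05) and CRR21 (0.56). In samples 1 and 2 alone 1 rose, OTP70 (0.46), and 0 fell. There mTERF9 (-0.42, limma adjusted p = 0.0537) and ATAB2 (-0.51, adjusted p = 0.0719) pointed the other way without passing, and CRR21 stood at 0.26. The WT mean of mTERF9 was 1.14 in samples 1 and 2 and 0.209 in samples 3 and 4, against 0.850 and 0.951 in tic40. Of the 13 plastid biosynthesis and redox genes, 3 rose and 8 fell in samples 3 and 4, and 2 rose and 1 fell in samples 1 and 2. In samples 3 and 4 AT3G52960, a type II peroxiredoxin, rose by 1.88, SIRB fell by 0.97 and PPDK, pyruvate phosphate dikinase, by 0.50. THIC, of thiamine synthesis, and SRX, sulfiredoxin, rose in samples 1 and 2 (0.55 each) and fell in samples 3 and 4 (-0.34 and -0.42). The difference between the pairs was not tested gene by gene, and it carries the difference between the WT pairs.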
